A study of Homo sapiens with 4 samples.

How the data were processed

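RNA sequencing of Huh7, a human hepatoma cell line, was analysed. Cells received either a lentivirus that expresses ISL1, a LIM-homeodomain transcription factor of heart, motor neuron and pancreatic islet development, or a blank lentivirus. There were 4 libraries, 2 per group, all from passage 3. Per the labels' protocols, total RNA was harvested with a Qiagen kit and libraries were made with Illumina's standard protocol, and sequenced on an Illumina HiSeq. Whether the duplicates came from separate cultures is not stated, so per-gene p-values measure only the spread between these libraries, which may be technical. One library of the ISL1 group carries the name of ISL2 in its title. It was placed with ISL1 because the design names only ISL1 and blank virus, each in duplicate, and its levels of both genes are given first.

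The authors deposited 1 table per library with gene symbols and RPKM values (reads scaled by transcript length and by the mapped reads of the library), with no read counts. CASAVA 1.4, BWA and the build hg19 are named, per the submitters' processing notes; the gene annotation and the counting program are not given in the sources used here. No coordinates are printed, since the reference at hand was of another build. The replicate 1 tables of both groups listed the same 16640 genes and the replicate 2 tables the same 17197, of which 14055 were in all 4 tables, 2585 only in replicate 1 and 3142 only in replicate 2. The replicate 1 tables held 0.0001 where the replicate 2 tables held 0. The 2 replicate numbers were thus processed differently, and each number holds 1 library of each group. Differences or levels within each replicate number (a pair) are therefore printed beside most pooled values, but not for AADAC, CA4, MYH4, C1RL and STIP1.

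Depth was recovered from the steps between low RPKM values. Within a pair, 97.1% (replicate 1) and 96.3% (replicate 2) of genes below 5 RPKM in both libraries stood in ratios of whole numbers up to 500, within a relative tolerance of 1e-07, against 2.14% and 2.08% for ratios multiplied by an arbitrary factor. The depths that make gene lengths whole were 32289510 reads (first control), 37134267 (first ISL1), 34274524 (second control) and 29429964 (second ISL1), found from 80 of 100 starting genes in replicate 1 and 54 of 100 in replicate 2. One read in a transcript of 1 kb was then worth 0.031, 0.0269, 0.0292 and 0.034 RPKM, in the same order, and a count of 0 allowed up to 0.0929, 0.0808, 0.0875 and 0.102 RPKM (3 reads in 1 kb). These limits cover counting error only. The reads behind a gene are known only up to a common factor, so no count model was run.

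Values were joined by symbol; no symbol was repeated. Genes in all 4 tables with at least 1 RPKM in at least 2 libraries were kept (11085). The main test was limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend, 2 residual degrees of freedom plus the trend) on log2(RPKM + 1), 2 libraries against 2, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. An exact permutation test of 2 against 2 cannot give a p below 0.333. Gene lists were tested with limma's camera (preset inter-gene correlation 0.01), with an estimated correlation and with fry, adjusted over the 30 of 36 lists with at least 5 tested members. With the preset correlation, camera compares members with the other genes. Its small p-values therefore rest on the spread across genes, not on the spread between libraries. Within each pair there is 1 library per group and no test. A list's median difference was given its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries only. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Numbers of RefSeq transcripts per gene were taken by symbol for 99.4% of the tested genes.

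The design, the lists and the rule for named genes were fixed before the data were examined. The rule takes ISL1 and ISL2, then the 12 largest rises and falls past the threshold. Where fewer than 5 passed, it takes the 10 genes of each direction with the smallest p among those with both ISL1 libraries on the same side of both controls, given as values. It then takes up to 4 members of each list with the smallest p. Some genes that the rule takes are not reported here. Genes named outside the rule were chosen after their values were seen. Among them, CDK1, MKI67, FOXM1, HSPA1A, HSPA8, HIST2H2BE, SLC7A11, AKR1B10, NPPA, TNNT2, HBB, MALAT1 and NEAT1 carry no further remark.

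The 36 lists covered the LIM complex, reported ISL1 targets, G1/S, G2/M, MYC, p53, apoptosis, hepatocyte secreted proteins, liver transcription factors, xenobiotic and bile acid metabolism, cholesterol, fatty acids (synthesis, oxidation), glycolysis, gluconeogenesis, the amino acid and unfolded protein responses, heat shock, hypoxia, interferon, NF-kB, JAK/STAT, Wnt, TGF-beta and EMT, immediate early genes, oxidative stress and metallothioneins, neuronal genes, ribosomal proteins, oxidative phosphorylation, histones and housekeeping genes. The 6 lists with too few tested members were cardiac progenitor, pancreatic endocrine, immune, stromal and endothelial, other cultured line, and mitochondrial and small RNA genes. Lists of heart muscle genes, erythroid genes and the neighbours of CACNA2D1 were written later, after the first such genes had been seen, and their counts leave those genes out. Alternatives changed the pseudocount, the filter, the scaling, the variance trend and the treatment of missing genes, added the replicate number as a block, and left out each library.

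The test was tried on simulated data of this comparison (11085 genes, 200 of them changed, 50 of each size). At the levels of these files and the real spread of the pair differences, the unblocked test recovered 0% of changes of 1, 2, 3 and 4 on the log2 scale, because the gap between replicate 1 and replicate 2 tables enters its error. With the replicate block, it recovered 26%, 98%, 100% and 100%, with 6 false calls. With replicate 2 levels in every library, the unblocked test recovered 34%, 96%, 100% and 100%, with 13 false calls. The simulated noise had 1 size for all genes, which real libraries do not, and each simulated change was the same in both pairs. The recovered shares can therefore overstate power in these libraries, where the blocked test did not call ISL1 (log2 fold change 6.98, limma adjusted p = 0.496).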

Results

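Gene expression was measured by RNA sequencing in Huh7 hepatoma cells given ISL1 lentivirus (2 libraries) or blank lentivirus (2 libraries), at depths of 29429964 to 37134267 reads. The comparison asks which transcripts differ once ISL1 is expressed. ISL1 itself was higher in both ISL1 libraries, by very different amounts. It stood at 0.0454 RPKM in the first control and 8.22 in the first ISL1 library, and was listed at 0 in the second control and at 1801 in the second ISL1 library. The differences were 3.14 and 10.82 on the log2(RPKM + 1) scale, and the pooled log2 fold change was 6.98 (SE 2.87, n = 2 per group, limma adjusted p = 1.00). ISL2, a close relative, went from 4.57 to 2.08 RPKM in the first pair and from 3.23 to 13.2 in the second, the pair whose ISL1 library carries the name of ISL2 in its title.

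Most mitotic genes (27 of 30), heat shock genes (9 of 13) and replication-dependent histones (10 of 15) stood higher with ISL1 in both pairs. Single genes such as TSPAN8, GUCY2C, RBP2 and SERPINC1 stood lower in both, which the rule that named them requires. The 3 lists passed camera with its preset correlation and not with an estimated one (adjusted p = 0.988 for each). The estimate rests on 2 residual degrees of freedom, so this miss does not argue against the lists. The pass does not establish them either, since it takes a correlation of 0.01 between members as given. With fry no list passed (smallest adjusted p = 0.996, and 0.688 with the replicate block). No single gene passed the pooled limma test at an adjusted p of 0.05 (0 of 11085), where 15 genes had an unadjusted p under 0.05 against 554 expected by chance. The replicate block gave 0 as well, with 260 unadjusted. The pooled test recovered no simulated change at these levels, so its count says nothing about absence. The blocked count does not show absence either, since the blocked test did not call ISL1 itself (limma adjusted p = 0.496). The differences of ISL1 were unlike in size (3.14 and 10.82), so this miss does not measure power for changes alike in both pairs. Both ISL1 libraries lay above both controls for 612 genes and below both for 563 (5.52% and 5.08%), where chance gives 33.3% either way for unpaired libraries; these pair by replicate number, so that share does not hold for them.

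The libraries resembled one another by replicate number rather than by treatment. Across the 11085 genes, Pearson's r was 0.976 between the first control and the first ISL1 library and 0.931 between the second ones, against 0.582 between the controls and 0.586 between the ISL1 libraries (genes are not independent replicates). Between the controls r was 0.912 over the 3235 genes with 1 RefSeq transcript, 0.626 over the 2219 with 2 and 0.450 over the 5565 with 3 or more. The tested genes stood lower in the replicate 1 tables by a median of -0.96 on the log2 scale.

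**Figure D1:**
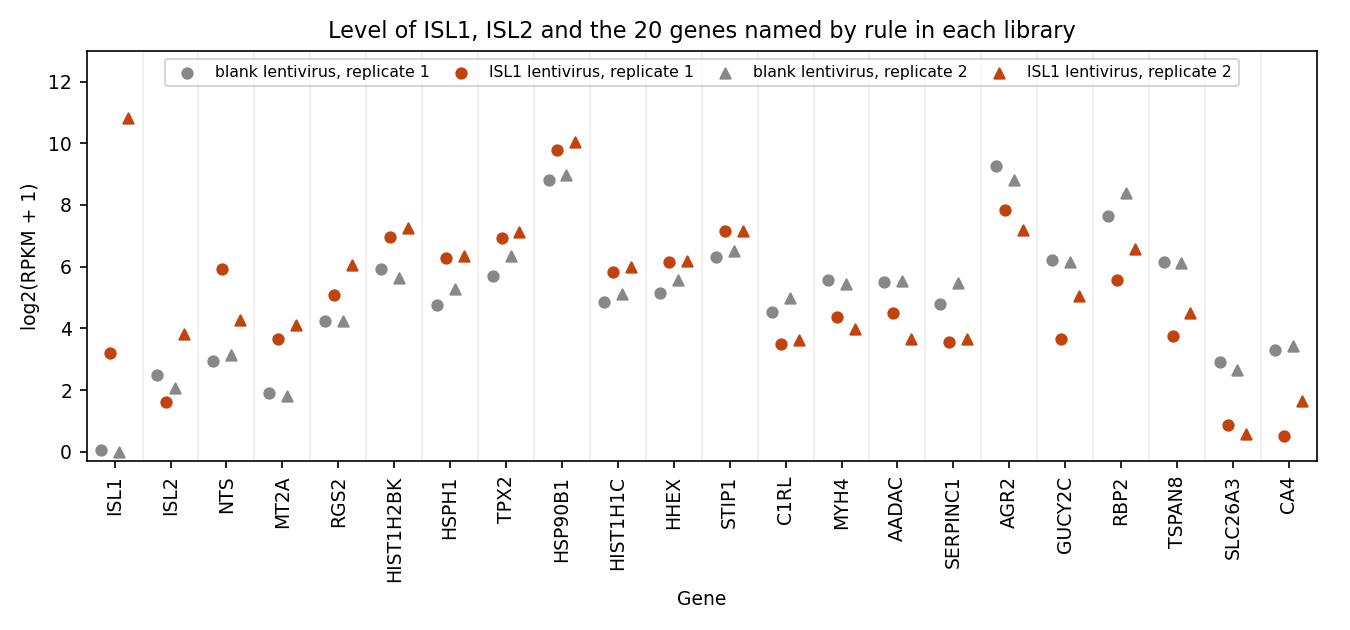
Level of ISL1, ISL2 and the 20 genes named by rule (x axis) in each library, as log2(RPKM + 1) (y axis); each point is 1 library, circles are replicate 1 and triangles replicate 2, with no mean or error drawn. ISL1 differed by 3.14 in the first pair and 10.82 in the second. The 20 genes were chosen for having both ISL1 libraries on the same side of both controls.

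The 10 genes with the smallest p in the higher direction were NTS, MT2A, RGS2, HIST1H2BK, HSPH1, TPX2, HSP90B1, HIST1H1C, HHEX and STIP1, none past the threshold (limma adjusted p = 1.00 for each). NTS, which encodes the neuropeptide neurotensin, went from 6.68 to 60.1 RPKM in the first pair and from 7.76 to 18.3 in the second. MT2A, a metal-binding metallothionein, went from 2.72 to 11.5 and from 2.504 to 16.3 RPKM. HSPH1, a large heat shock protein, went from 26.0 to 76.3 and from 37.9 to 81.2 RPKM. HHEX, a homeobox factor of liver development, went from 34.6 to 69.9 and from 46.4 to 72.0 RPKM. Their pooled log2 fold changes were 2.06 (SE 0.73), 2.03 (SE 0.60), 1.30 (SE 0.33) and 0.81 (SE 0.31). RGS2, a regulator of G-protein signalling, differed by 0.85 and 1.82 on the log2 scale in the first and second pair.

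In the lower direction the 10 genes were AADAC, SLC26A3, CA4, RBP2, MYH4, TSPAN8, GUCY2C, AGR2, C1RL and SERPINC1, again with a limma adjusted p of 1.00 for each. TSPAN8, a tetraspanin, went from 69.7 to 12.5 RPKM in the first pair and from 69.2 to 21.8 in the second. GUCY2C, the guanylyl cyclase receptor of the intestinal epithelium, went from 74.2 to 11.6 and from 70.1 to 32.1 RPKM. RBP2, an intestinal retinol-binding protein, went from 199.7 to 46.4 and from 336.9 to 94.7 RPKM, and AGR2, a disulfide isomerase of secretory epithelia, from 616.4 to 228.8 and from 443.6 to 144.0. SLC26A3, a chloride and bicarbonate exchanger of the gut, went from 6.56 to 0.837 and from 5.34 to 0.493 RPKM. SERPINC1, which encodes antithrombin, went from 26.5 to 10.8 and from 43.3 to 11.6 RPKM. Pooled log2 fold changes were -2.01 (SE 0.40) for TSPAN8, -1.84 (SE 0.59) for GUCY2C, -1.95 (SE 0.53) for RBP2 and -1.52 (SE 0.43) for SERPINC1.

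The list of mitotic (G2/M) genes had 27 of its 30 tested members higher in both pairs. Its median difference was 0.89 in the first pair and 0.63 in the second, each at percentile 100 of the random lists. CCNB1, the cyclin of mitotic entry, went from 32.9 to 93.3 and from 63.3 to 109.7 RPKM, and CDC20, an activator of the anaphase-promoting complex, from 44.4 to 79.7 and from 55.1 to 149.2. PLK1, a mitotic kinase, differed by 0.99 and 0.98 on the log2 scale and TPX2, a spindle assembly factor, by 1.23 and 0.78. CDK1 (0.98 and -0.11), MKI67 (0.24 and -0.46) and FOXM1 (0.19 and -0.12) were the members with opposite signs. The list passed camera with its preset correlation (adjusted p = 1.28e-18), and not with an estimated correlation (adjusted p = 0.988).

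Of 13 tested heat shock genes, 9 were higher in both pairs and 4 had opposite signs. The medians were 0.96 and 0.49, at percentiles 100 and 99.3 (camera adjusted p = 2.42e-10, and adjusted p = 0.988 with an estimated correlation). BAG3, a co-chaperone, went from 9.71 to 15.4 and from 10.8 to 46.7 RPKM, and HSPB1, a small heat shock protein, from 73.7 to 124.7 and from 113.3 to 282.3. HSPA1A and HSPA1B are near-identical copies whose reads cannot be told apart with certainty; HSPA1A went from 1.65 to 5.91 and from 40.4 to 250.9 RPKM. HSPA8 differed by 1.80 in the first pair and by -0.19 in the second.

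Replication-dependent histones, whose transcripts mostly lack poly(A) tails, had 10 of 15 members higher in both pairs and none lower in both. Many members were low, and a minimum of 5 RPKM in 2 libraries left too few to test. Their medians were 0.39 and 1.10, both at percentile 100 (camera adjusted p = 2.10e-13, and adjusted p = 0.988 with an estimated correlation). HIST1H1C, a linker histone, went from 28.1 to 56.2 and from 33.3 to 62.9 RPKM, and HIST1H2BK from 59.9 to 123.8 and from 48.4 to 150.2. HIST2H2BE differed by -1.28 and 3.03. Histone genes are a family of close copies, so single members are uncertain.

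In the list of oxidative stress genes and metallothioneins, the members went different ways. The metallothioneins MT1E, MT1F, MT1X and MT2A were higher in both pairs, by 0.56 to 1.75 in the first and 1.67 to 2.31 in the second on the log2 scale, while SLC7A11, the cystine transporter, differed by -1.65 and 2.17 and AKR1B10, an aldo-keto reductase, by -2.15 and 0.79. The list had 11 of 23 members higher in both pairs and medians of 0.06 and 0.79 (camera adjusted p = 1.21e-05, and adjusted p = 0.988 with an estimated correlation). With a minimum of 5 RPKM the first median was -0.25. Without the second ISL1 library the camera adjusted p was 0.216, and without the second control 0.353. Metallothioneins are close copies too.

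**Figure D2:**
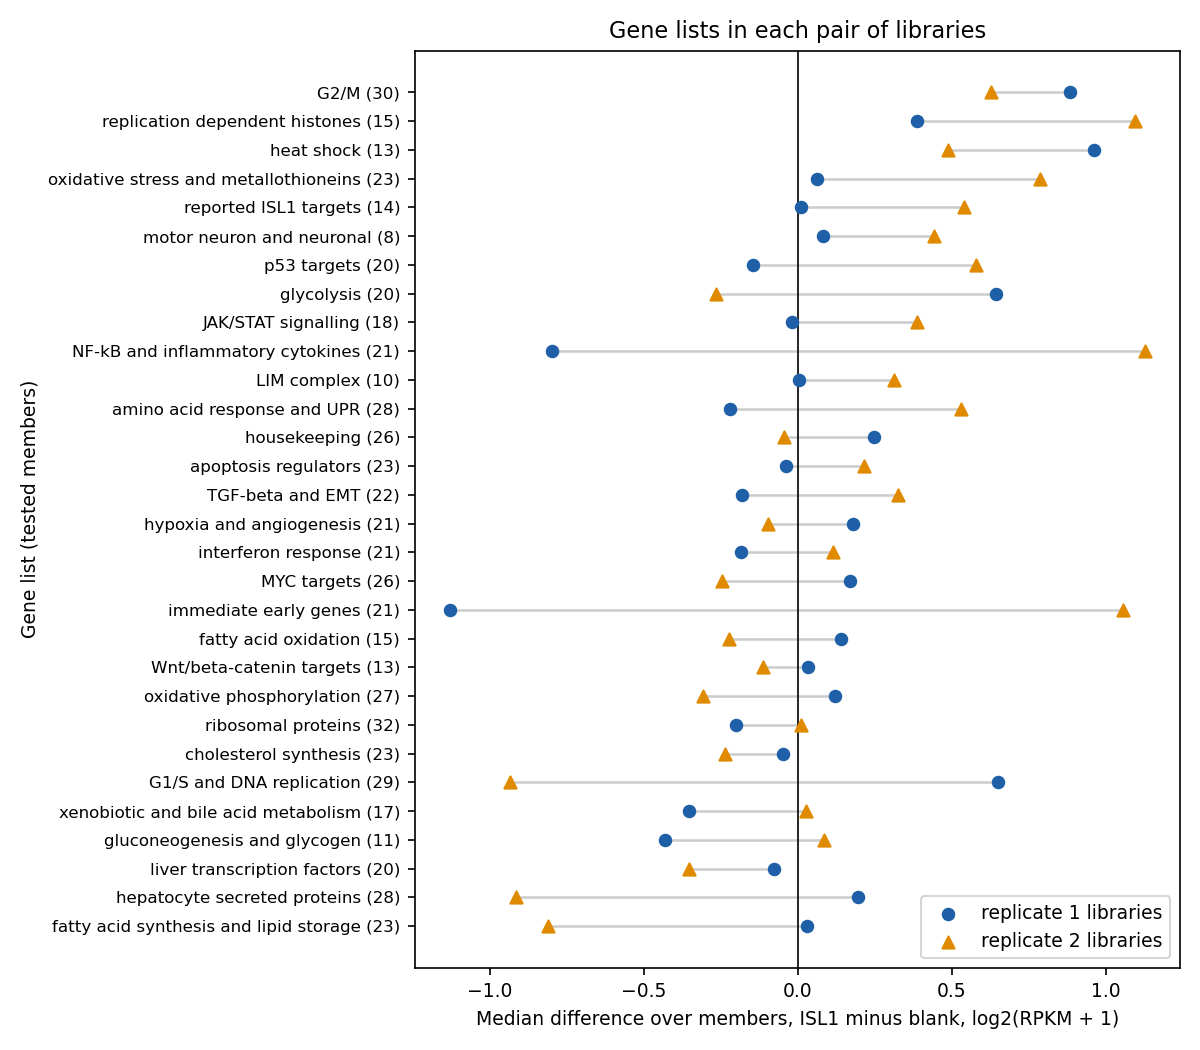
Median difference between the ISL1 and the blank library over the tested members of each list (x axis, log2(RPKM + 1)), 1 list per line with its tested members in brackets; circles are the replicate 1 pair, triangles the replicate 2 pair, and the line joins them, with no error drawn. G2/M genes (0.89 and 0.63) lie on the higher side in both pairs, and immediate early genes (-1.13 and 1.06) on opposite sides.

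Other lists stood on opposite sides in the 2 pairs. G1/S and DNA replication genes had a median of 0.65 in the first pair and -0.93 in the second (percentiles 100 and 0), with 23 of 29 members of opposite sign. Immediate early genes had medians of -1.13 and 1.06 (percentiles 0 and 100), with 18 of 21 of opposite sign; JUN, a subunit of AP-1, went from 69.6 to 28.2 and from 20.1 to 150.9 RPKM. NF-kB and cytokine genes had medians of -0.80 and 1.13 (percentiles 0 and 100), again with 18 of 21 of opposite sign; IL8, a neutrophil chemokine, went from 59.3 to 3.09 and from 2.95 to 8.50 RPKM. Glycolysis genes had medians of 0.64 and -0.27. Pooled, none of these 4 lists passed camera (adjusted p = 0.574, 0.574, 0.312 and 0.639).

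Hepatocyte secreted proteins and fatty acid synthesis genes were lower mainly in the second pair. The secreted proteins had medians of 0.20 and -0.92 (9 of 28 lower in both pairs, 17 of opposite sign), and the fatty acid genes 0.03 and -0.81 (5 of 23 lower in both, 17 opposite). APOB, the apolipoprotein of VLDL, went from 211.6 to 264.3 and from 394.4 to 84.2 RPKM, TTR, a thyroid hormone carrier, from 481.7 to 372.7 and from 406.1 to 161.7, and FASN, the fatty acid synthase, from 91.9 to 107.3 and from 92.3 to 24.2. RBP4, the retinol carrier of plasma, was higher in both pairs, from 842.0 to 1129 and from 914.8 to 1096 RPKM. Liver transcription factors had medians of -0.08 and -0.35, and xenobiotic and bile acid metabolism -0.35 and 0.03, the latter turning to -0.28 with median-ratio scaling and to -0.07 with the other scalings. Within the latter list GSTA2, a glutathione transferase, differed by -2.17 and -1.34. Pooled, the 4 lists passed camera in the lower direction (adjusted p = 7.27e-06, 0.00776, 0.00216 and 0.00132), and none with an estimated correlation (adjusted p = 1.00, 1.00, 1.00 and 0.988). Each lost its call without the second control or with another library left out. Without the second ISL1 library the secreted proteins had camera adjusted p = 0.512 in the other direction and the fatty acid genes 0.915. Without the second control both lists and the transcription factors had 0.353, and without the first control the xenobiotic list had 0.858.

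Targets of the amino acid and unfolded protein responses had medians of -0.22 and 0.53, with 18 of 28 members of opposite sign. CALR, an endoplasmic reticulum chaperone, went from 383.5 to 1155 and from 879.4 to 1088 RPKM, and HSP90B1, another chaperone of that compartment, from 450.1 to 872.6 and from 506.0 to 1044. The list passed camera (adjusted p = 2.62e-05; adjusted p = 0.988 with an estimated correlation) and did not without the second control (0.605) or the second ISL1 library (0.340). Genes described as ISL1 targets had medians of 0.01 and 0.54, with 7 of 14 higher in both pairs. Among them, CCNB1 and CCNB2 are also members of the G2/M list and CCNE1 of the G1/S list. ZEB1 and PAX6 were near the floor in the first pair and differed there by only 0.00603 and 0.0169. The others were SHH (0.0527 and 0.727) and SLIT2 (0.875 and 0.165). The list of reported targets was not tested without the cyclins. That list passed camera (adjusted p = 0.017; adjusted p = 1.00 with an estimated correlation) and did not without the second control (0.491), the first ISL1 library (0.182) or the second (0.210).

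The remaining lists did not pass camera. With the replicate block the LIM complex, neuronal and gluconeogenesis lists did (camera adjusted p = 0.0397, 0.0388 and 0.0397, and adjusted p = 0.828 for each with an estimated correlation). The LIM complex list holds the overexpressed gene itself and was not tested without it. Neuronal members such as GATA2 (0.0001 to 0.0850 RPKM), GATA3 (0.0807 to 0.0351) and SYT1 (0.0512 to 0.0278) were near the floor in the first pair. Among the remaining lists p53 targets had medians of -0.15 and 0.58 and 14 of 20 members of opposite sign, gluconeogenesis genes -0.43 and 0.08, interferon response genes -0.18 and 0.11, and TGF-beta and EMT genes -0.18 and 0.32. CDH2, N-cadherin, went from 23.7 to 40.5 and from 20.4 to 37.3 RPKM, and CDH1, E-cadherin, from 57.7 to 38.7 and from 110.0 to 74.5. MMP14, a membrane metalloproteinase, differed by -0.45 and -0.50 on the log2 scale and EPCAM, an epithelial adhesion molecule, by -1.17 and -0.14. The medians were 0.17 and -0.24 for MYC targets, -0.04 and 0.22 for apoptosis regulators, -0.05 and -0.24 for cholesterol synthesis, 0.14 and -0.22 for fatty acid oxidation, 0.18 and -0.10 for hypoxia, -0.02 and 0.39 for JAK/STAT signalling and 0.03 and -0.11 for Wnt targets. They were 0.00 and 0.31 for the LIM complex, which holds ISL1, 0.08 and 0.44 for neuronal genes, -0.20 and 0.01 for ribosomal proteins, 0.12 and -0.31 for oxidative phosphorylation and 0.25 and -0.04 for housekeeping genes. DKK1, a Wnt antagonist, went from 9.23 to 225 RPKM in the first pair and from 52.8 to 38.5 in the second. Median, mean and test differed in sign for the interferon, Wnt, TGF-beta and immediate early lists.

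**Figure D3:**
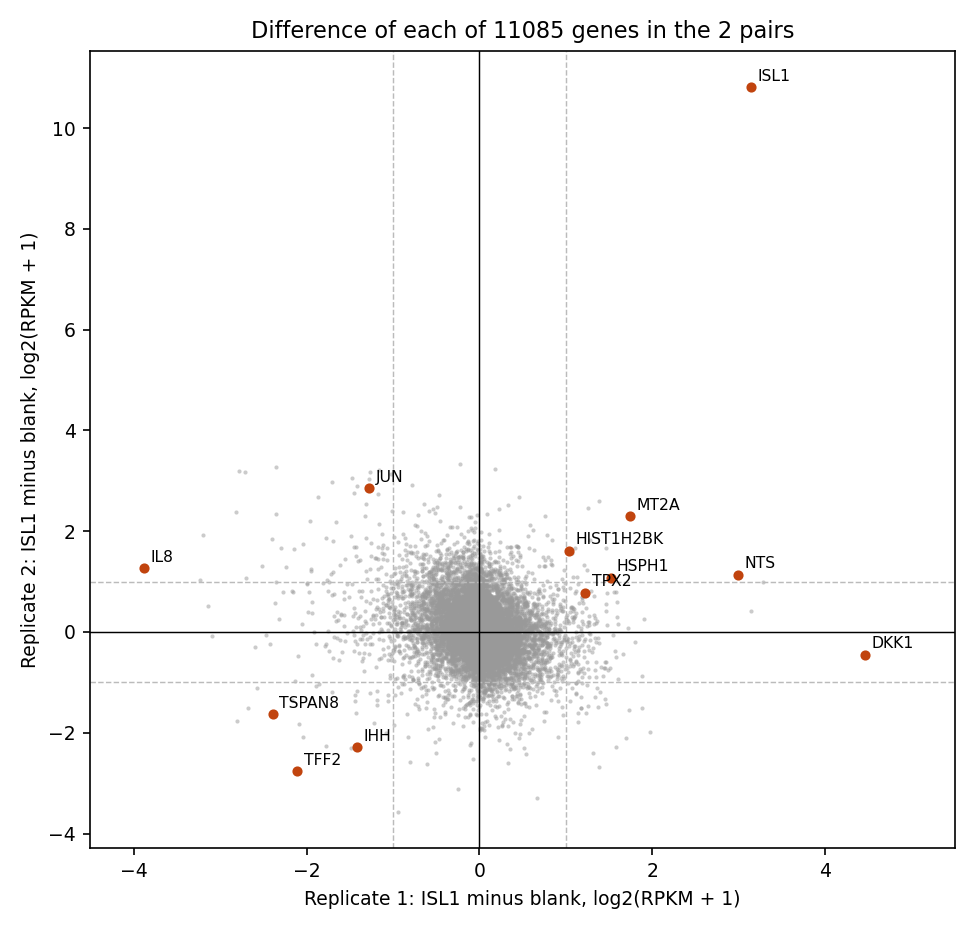
Difference between the ISL1 and the blank library on the log2(RPKM + 1) scale in the replicate 1 pair (x axis) and the replicate 2 pair (y axis); each point is 1 of 11085 genes, dashed lines mark 2-fold differences, and labelled points are genes named in the text. More genes were 2-fold lower in the first pair and higher in the second (72) than 2-fold higher in both (15) or lower in both (26).

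Counting single genes, 15 were at least 2-fold higher in both pairs and 26 at least 2-fold lower in both, against 12.3 and 9.64 for independent lists. Higher in 1 pair and lower in the other were 29 (first higher) and 72 (first lower), against 6.99 and 17.0. Spearman's rho between the pairs' differences was -0.216 and Pearson's r -0.191 across genes, which are not independent replicates, and 42.2% of genes had the same sign in both. Chosen after their values were seen, the genes 2-fold lower in both pairs included TFF1 and TFF2, trefoil peptides of mucous epithelia. TFF1 went from 66.4 to 9.54 and from 168.6 to 58.7 RPKM and TFF2 from 23.7 to 4.73 and from 186.9 to 26.6. They also included SI, sucrase-isomaltase (-1.44 and -1.36), IHH, a hedgehog ligand (-1.41 and -2.29), PECAM1, an endothelial adhesion molecule (-1.48 and -2.31), and UGT2B11, a glucuronosyltransferase (-1.77 and -2.27).

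Members of the lists of other cell types were mostly near or below 1 RPKM and are given as values. Heart transcripts were present in the second ISL1 library. NPPA, the atrial natriuretic peptide, stood at 22.0 RPKM there against 0.544 in the second control, 0.686 in the first control and 0.690 in the first ISL1 library, and TNNT2, cardiac troponin T, at 10.6 against 0.681 in its control. The second control held globin transcripts instead, with HBB at 398 RPKM against 0 in the second ISL1 library and 0.0495 in the first control. The gene groups of the second pair were read in these same libraries. The islet factor PDX1 went from 2.95 to 0.890 and from 4.77 to 17.4 RPKM. The leukocyte gene CD68 went from 2.60 to 1.86 and from 73.5 to 53.9 RPKM, and the stromal gene TAGLN from 0.315 to 1.93 and from 4.49 to 7.22. CAV1, from the list for other cultured lines, went from 0.222 to 0.210 and from 6.38 to 16.4 RPKM. Of the nuclear non-coding RNAs, MALAT1 went from 64.7 to 38.6 RPKM and NEAT1 from 165 to 79.6 in the first pair; the replicate 2 tables do not list them.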

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

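In the weighing of these results, the tests of blood-containing heart tissue, of CACNA2D1 against heart genes, of swapped labels, of the level of ISL1 and of cultures as the cause of lower levels in the replicate 1 tables were chosen after the results were seen, as was the chance value for the neighbours of CACNA2D1.

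Genes listed only in the replicate 2 tables lay outside the comparison, and 11 of them stood at 1 RPKM or more in the second ISL1 library and at 0.1 or less in its control. The heart and muscle genes among them were MYL7 (12.2 RPKM), MB (5.93), MYL2 (1.51), MYH6 (1.18) and PLN (1.01), each listed at 0 in the control. The others were EGR2 (2.02), LOC729974 (1.22), PTHLH (1.22), PTGDS (1.06), LOC100132859 (1.04) and REG3A (1.03).

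Transcripts typical of other tissues split the replicate 2 libraries. Against RNA of blood-containing heart tissue in the second ISL1 library stands HBB, at 0 RPKM there beside HBA1 at 0.708 and HBA2 at 0.656. RNA of heart muscle cells stays open. Of 34 heart muscle genes not looked at before, 21 were at least 0.1 RPKM higher than in the control, between the bounds set. Of 2580 genes below 0.1 RPKM in the control, 18.3% were. These shares are not of like genes. Some of the 34 heart genes, such as TNNI3 (0.337) and NEXN (0.754), stood above 0.1 RPKM in the control, and 4 stood at 1 RPKM or more. Heart muscle RNA does not account for CACNA2D1, a calcium channel subunit at 902 RPKM against 0.0611 in the control. CACNA2D1 stood 41.0 times above the highest heart gene (NPPA, 22.0). In the first pair CACNA2D1 stood at 0.0162 RPKM in the control and 0.0282 in the ISL1 library. Activation of its chromosome region stays open. Of 9 listed neighbours, 3 (SEMA3E, CD36 and GNAI1) were at least 2-fold higher and at 1 RPKM or more, against 7.77% of genes. The chance value for this count (binomial p = 0.0276) passes a limit of 0.05 and not one of 0.01. The highest of the 3, GNAI1, went only from 6.74 to 16.3 RPKM. The count therefore cannot tell whether activation of the region accounts for the level of CACNA2D1. For the globins of the second control library (HBB 398, HBA1 354, HBA2 248 RPKM), 6 of 21 erythroid genes were higher. This was under the bound set in advance for excluding RNA of erythroid cells. That bound was set wrongly, as judged after the count, since it weighed near-floor genes like the alpha globins of the same list. HBD (29.6 RPKM against 0) and ALAS2 (2.42 against 0.0352), seen before like HBB and left out of the count, were higher too. Erythroid cells cannot be told apart from other sources. In the first pair 20 of these heart muscle genes were listed. With ISL1, 1 of the 20 was at least 0.1 RPKM higher and 4 were lower by as much, at the lower level of ISL1 there. ISL1 differs between the replicate 2 libraries too, so an effect of ISL1 on the heart genes remains untested.

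The 2 pairs differed in opposite ways for many genes, and this difference was not tested. Swapped labels in 1 pair are argued against by ISL1 itself, higher in the ISL1 library of both pairs by at least 3.14 on the log2 scale. Reads lost for genes with several transcripts are argued against by the 3235 genes with 1 RefSeq transcript, where Spearman's rho was -0.236. The level of ISL1, 219 times higher in the second ISL1 library than in the first, and differences between cultures cannot be told apart, because the design has 1 library at each level.

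Tested genes stood lower in the replicate 1 tables. The gap was a median of -0.20 on the log2 scale for genes with 1 RefSeq transcript, -1.61 with 2 and -2.30 with 3 or more. The difference of -2.09 between the last and the first group is consistent with reads shared between transcripts of a gene being left out of the replicate 1 tables, as a hypothesis. Reads shared with processed pseudogenes are argued against, since the gap was 0.15 higher, not lower, for genes that have a named one. Differences between cultures as the whole cause are argued against, since the difference between genes with 3 or more transcripts and genes with 1, taken within 5 bins of level, was -0.85 at its smallest; cultures as part of the cause stay open. Each group has 1 library in each kind of table, so no effect of ISL1 on this gap was tested.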

How the results depend on the processing

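Alternatives on the minimum of 1 RPKM in each pair and on genes with 1 RefSeq transcript were chosen after seeing the data. The count of genes past the threshold was 0 in each alternative except quantile normalization, which gave 1 gene, ISL1 (log2 fold change 6.76, adjusted p = 0.00998, against 0.347 to 1.00 in the others); the cause was not tested. ISL1 was higher in every alternative, from 3.17 without the second ISL1 library to 10.78 without the first, which follows from the library left out. The replicate block left the log2 fold change of ISL1 at 6.98 (adjusted p = 0.496) and the count at 0. Libraries of the same number deviated together from their group means (r = 0.882; chosen after seeing the data, 0.361 over genes with 1 RefSeq transcript and 0.914 with 3 or more). Leaving out 1 library took the median log2 fold change of all genes from 0.03 to between -0.60 and 0.67, since tested genes stood lower in the replicate 1 tables, and its lone library is assumed to vary like the others.

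The 10 lists that passed camera became 13 with the replicate block (the same 10 among them), 8 to 15 with a library left out, and 0 with an estimated correlation or with fry; the cause was not tested. The G2/M, heat shock and histone lists kept direction and side in every alternative of the preset camera test that could be run (a minimum of 5 RPKM left too few histones, and 1 RefSeq transcript too few reported ISL1 targets); the other 7 lost the call in some, and hepatocyte secreted proteins reversed without the second ISL1 library (adjusted p = 0.512; 1.70e-12 without the first). Adjusted over the list alone, 0 members passed without the block. With it, 10 passed as higher (ISL1, BAG3, HSPA1A, HSPA1B, HSPB1, HSPH1, MT1E, MT1F, MT1X and MT2A) and 4 as lower, among them PLG, SERPINC1 and GSTA2.

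Genes 2-fold higher in both pairs were 31 with a pseudocount of 0.1 (34.1 for independent lists), 18 with 0.5 (18.3) and 9 (7.93) among genes with 1 RefSeq transcript. Those lower in both were 69 with 0.1 and 41 with 0.5. Opposite ones (first higher, then first lower) were 62 and 161 with 0.1, 52 and 54 with median-ratio scaling, and 18 and 42 with 1 transcript. Lower pseudocounts admit low genes and the set with 1 transcript is smaller. With median-ratio scaling the counts were close to each other, unlike 29 and 72. The counts for independent lists moved too, from 6.99 and 17.0 to 19.1 and 8.16, so first lower genes still exceeded theirs. Spearman's rho stayed below 0 throughout. Of 518 list medians by pair, 510 moved by under 0.5. The others were the NF-kB list in the first pair (-1.74 with a pseudocount of 0.1, -1.92 with 1 RPKM in each pair, -2.02 with 1 transcript), histones in the second (1.61 with 0.1) and, with 1 transcript, p53 (-1.99995) and hypoxia genes (0.81) in the first and heat shock (1.66) and fatty acid synthesis genes (-1.32) in the second. Another scaling, filter or gene set turned the sign of medians between -0.43 and 0.25, those of apoptosis, liver factor, cholesterol, JAK/STAT, reported ISL1 target, gluconeogenesis, unfolded protein, oxidative stress and housekeeping genes in the first pair and of xenobiotic, gluconeogenesis, interferon, ribosomal, apoptosis and hypoxia genes in the second. Median-ratio scaling moved the median of all genes to 0.09 in the first pair and -0.12 in the second.

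For the 20 genes named by rule and ISL2, 369 of 370 alternatives kept the direction and none passed the threshold. The exception was ISL2, at -0.65 without the second ISL1 library and 1.55 without the first, since it differed in opposite ways in the pairs.

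Count models were not run, since the files hold RPKM, and summing repeated symbols was void, as none repeats.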

Other observations

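Genes outside the comparison, because they were low or missing in 1 pair, held some of the largest differences. In the first pair NPTX2, a neuronal pentraxin, went from 0.249 to 5.79 RPKM, SERPINA7, which encodes thyroxine-binding globulin, from 0.310 to 6.13, and UCA1, a long non-coding RNA, from 18.1 to 1.13. GAS5, a non-coding RNA that hosts small nucleolar RNAs, went from 468 to 138 RPKM there. In the second pair ATF3, a stress-responsive transcription factor, went from 5.04 to 89.1 RPKM, FOSB, an AP-1 subunit, from 0.325 to 10.1, and HSPA6, a strictly inducible heat shock protein, from 0.635 to 20.6. HSPA6 stood at 0.0581 and 0.0303 RPKM in the first pair. CLDN2, a tight junction protein, went from 7.44 to 0.487 RPKM, and UGT2B10, a glucuronosyltransferase, from 8.70 to 0.706, both in the second pair. These are single libraries with no replicate check, chosen by the size of their difference.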
